A study of Drosophila melanogaster with 2 samples.

How the data were processed

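The series measured where a tagged form of CG2129 sat on the genome of Drosophila melanogaster embryos. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done, per the labels, on whole embryos aged 0 to 4 h from transgenic flies that carry a fusion of CG2129 with enhanced green fluorescent protein (eGFP). The protein was pulled down with an antibody against GFP. Peaks are read here as DNA that came down with the tag, and nonspecific recovery was not assessed. Chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels. The 2 samples are biological replicates 1 and 2 of this 1 group, so the design holds no contrast between conditions. A control experiment that the labels name was not analysed here.

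The authors' deposited files are peak lists on the dm6 assembly, per the labels and the readme text beside them. Each replicate has a ranked list and a thresholded list of its own. For the replicates pooled there are 2 ranked lists, a thresholded list and a conservative thresholded list. The aligner, the peak caller and their versions are not given in the sources used here. Each peak has a start, an end and a summit, and a signal that the authors' caller wrote. The scale of that signal is not stated in the deposited files, so its ratios and log2 differences have no known unit. Signals were ranked and compared between peaks of a list, and correlated between the lists of the 2 replicates. The deposited score in each list follows from the irreproducible discovery rate (IDR) and is capped at 1000. The IDR is the expected share of peaks that would not repeat between the rankings compared. Which rankings were compared for each list is not known here. Lists of 1 replicate carry it too, and the 2 pooled ranked lists differ at a summit by CG2129 (−log10 IDR 1.53 and 2.51). Passing it therefore does not mean presence in both replicates. The peaks at Tm1 and Ir76a matched none in either replicate's thresholded list. Every peak of the thresholded lists passed an IDR of 0.01, as tested on the scores and on the ranked lists. Columns that hold other per-replicate values inside the ranked lists were left out, because nothing ties them to a sample.

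The pooled thresholded list of 2067 peaks was the main set. It keeps 2067 of the 2117 pooled ranked peaks at that IDR, and the 50 that it leaves out are described in the closing section. The deposited readme names 2 further input files of each list without saying what they hold. The conservative list has 2017 peaks, of which 1717 are also in the main set at the same coordinates, so it is not a subset. Peaks on the arms X, 2L, 2R, 3L, 3R, 4 and Y were analysed, which are 2066 of the main set. Read depth is not known from these files. Intervals on shares are 95% exact Clopper-Pearson intervals and cover counting error only.

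Genes came from Ensembl release 115 on BDGP 6.54, whose arm coordinates are those of dm6, and sequence from the NCBI copy of Release 6. Arm lengths in the sequence were compared with the peaks, none of which ran past an arm's end. Annotated transposable elements were left out, which gave 18277 genes with 24111 transcription start sites (TSSs). A gene was called bound when a summit lay within 500 bp of a TSS of that gene. Coordinates are counted from 1.

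The tests, the 22 gene lists, the 20 motifs, the rule for naming genes and most alternatives were fixed before the data were examined. Entries of a list that matched no symbol were left out, which removed 2 entries, nos and Trh. Of the dosage compensation list roX1 and roX2 were left out as not protein-coding, and 2 entries of the cellularisation list named the same gene. Lists were compared with all other protein-coding genes of the arms X, 2L, 2R, 3L, 3R and 4 by the two-sided Fisher's exact test. Gene classes and head to head gene pairs (another protein-coding TSS on the opposite strand within 500 bp upstream) were tested likewise. Arm shares were set against the share of sequenced bases by exact binomial tests, with the share of TSSs as a second reference. Feature shares were set against 1000 random placements of the summits on the same arms. The smallest p that these can give is 0.001 one-sided and 0.002 two-sided. Signal at promoters was compared by a permutation test of medians with 100000 resamples. Motifs and all 8-mers seen in 20 or more windows were counted within 100 bp of the summit and in a window centred 1000 bp away on a random side, and compared by the exact McNemar test. Motifs were also compared with an equal number of ranked promoter peaks outside the thresholded lists, matched on GC content in bins of 2%. These weaker peaks were not matched on distance from the TSS. P-values were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05. Peaks of the 2 replicates were called shared where they overlapped by at least 50% of either peak's length. P-values across genes or peaks describe this set of sites, since neighbouring genes can share a peak and are not independent replicates.

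Genes were named by rule: the 10 strongest peaks, the 5 strongest without a TSS within 500 bp, up to 4 bound genes with the strongest peak for each list that passed, 1 for each other list with a bound member, CG2129 itself, and up to 4 unbound genes in alphabetical order for lists bound less often. Of the genes that this rule names, 1 is not reported here. Alternatives changed the peak set, the promoter distance, the background, the assignment of peaks to genes, the overlap rule, the motif window and the k-mer length. Merging overlapping peaks and leaving out peaks with TATCGAT were added after seeing the data. CARCCCTR had been listed beforehand as motif 7 of the fly core promoter set, but the core of that motif is CAKCNCTR. CAKCNCTR was therefore added after seeing the data, and CARCCCTR is reported by its sequence alone.

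The tests were tested on simulated data. With bound genes drawn at random, 0.227% of 2200 list tests were called. Odds raised about 4-fold were planted in the 5 largest lists only, of 48 to 230 genes, and were recovered in 99.8% of tests. Recovery in smaller lists and of lowered odds was not simulated, so a small list that did not pass may still differ. Summits placed at random gave 0 calls in 400 motif tests and 0 in 78270 8-mer tests. Such summits were drawn from the whole arms and not from promoters, so they do not show how many calls promoter sequence alone would give. A motif planted in 2% of windows was recovered in 100% of 5 runs, and its 8-mer in 80%. Random draws gave calls in 1.14% of 1400 arm tests and 0% of 140 feature tests. The test of signal was called in 5% of 100 runs without a difference and in 98% with one of 0.5 on the log2 scale. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.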

Results

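Binding of CG2129-eGFP was mapped in whole embryos of 0 to 4 h, a span that covers the syncytial divisions, cellularisation and the start of gastrulation. CG2129 lies on the X chromosome (dm6, 8145839 to 8147855, plus strand). Its coding sequence encodes 465 residues with 10 matches to the C2H2 zinc finger pattern, a fold that often contacts DNA. The design has 1 group with 2 biological replicates, so values are compared between sites and not between conditions. The pooled set held 2067 peaks, replicate 1 on its own 1681 and replicate 2 on its own 1347. Peaks of the pooled set had a median length of 404 bp and covered 652 kb, or 0.476%, of the arms. Signals are the authors' values and ran from 6.02 to 511 in the pooled set, with a median of 77.6.

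Whether the replicates mark the same sites was asked first. The strongest pooled peak, at the proteasome gene Rpn6, ranked 3 by signal in replicate 1 and 1 in replicate 2, and the next, at mtSSB, ranked 2 in both. Of the 1675 peaks of replicate 1 on the arms, 64.3% (95% interval 62.0 to 66.6) were shared with replicate 2. Of the 1346 peaks of replicate 2, 80.2% (77.9 to 82.3) were shared with replicate 1. Random placement gave 0.338% and 0.424% on average (p = 0.001 for each, one-sided permutation test, the smallest it can give). Peaks not shared were the weaker ones, with a median signal of 36.2 against 64.3 in replicate 1 and 28.3 against 49.5 in replicate 2. Most of them were still present in the other replicate's ranked list, 494 of 598 for replicate 1 and 198 of 267 for replicate 2. Those ranked lists are long, with 40656 peaks on the arms for replicate 1 and 47464 for replicate 2. They cover 10.2% and 11.3% of the arms. In the pooled ranked list 8491 of 13945 protein-coding genes had a peak at a TSS. No chance value was computed for this presence, so it is weak evidence of agreement. Over 1040 matched peaks the log signals had a Spearman's rho of 0.738 (95% interval 0.709 to 0.765) and a Pearson's r of 0.748, which is a correlation across peaks and not across samples. Those peaks passed the threshold in both replicates, and over 11080 matched peaks of the 2 ranked lists rho was 0.487.

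**Figure D1:**
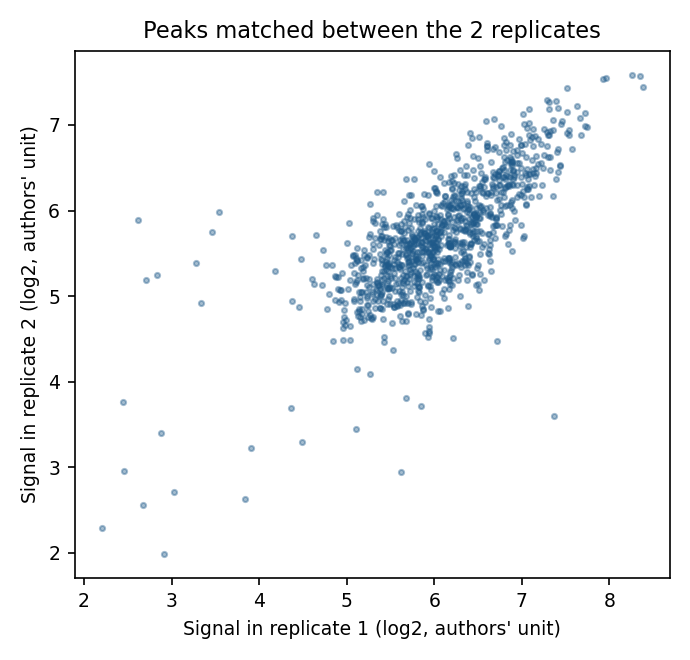
Signal of the 1040 peaks matched between the 2 replicates' own thresholded sets, replicate 1 on the x axis and replicate 2 on the y axis, both log2 of the authors' signal. Each point is a peak, and strong peaks in replicate 1 were strong in replicate 2 (Spearman's rho 0.738 among these peaks, which passed in both).

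The sites lay almost entirely at gene starts. Of 2066 summits, 1954 (94.6%, 95% interval 93.5 to 95.5) fell within 500 bp of a TSS, against 13.6% ± 0.751 (SD over 1000 placements) expected from random placement (p = 0.001, one-sided permutation test). The distance was short: 89.4% were within 200 bp, and the median promoter summit lay 38 bp upstream of the nearest TSS, with 71.9% of them upstream. Introns held 46 summits (2.23%, placed 39.6%), intergenic sequence 48 (2.32%, placed 27.0%), coding exons 7 (0.339%, placed 13.8%), 3' UTRs 8 (0.387%, placed 4.51%), non-coding exons 2 and 5' UTRs outside the promoter window 1. The classes add up to all summits, so the low shares outside promoters follow from the promoter excess. Promoter peaks had a higher median signal than the 112 others, 78.9 against 59.2 (log2 difference 0.41, p = 0.00029, permutation test). That difference was not past the threshold in the set of replicate 2 alone (0.20, permutation p = 0.0879). Nor did it pass among peaks found in both replicates' sets (0.13, permutation p = 0.389). Peaks not shared were the weaker ones, and whether leaving them out narrows such a difference was not tested.

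**Figure D2:**
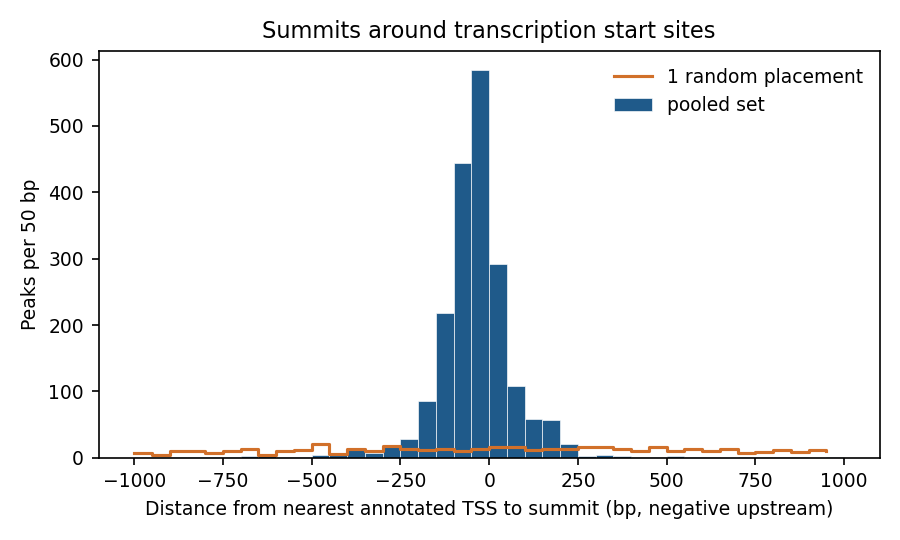
Number of pooled peaks per 50 bp by the signed distance of the summit from the nearest annotated TSS (x axis, bp, negative upstream), with 1 random placement of the same peaks as a line. Summits pile up just upstream of the TSS, with a median of 38 bp upstream, while placed summits are spread over the whole span.

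The 10 strongest peaks were all at promoters of protein-coding genes. The strongest (2R, 14752190 to 14752595, signal 511) lay 100 bp from the TSS of Rpn6, which encodes a subunit of the proteasome lid, and within 500 bp of a TSS of ave. The next lay at mtSSB, the mitochondrial single-stranded DNA-binding protein (3R, 16205103 to 16205498, signal 508), and at MESK2 and TAF1C-like (2R, 21501702 to 21502213, signal 500.1). The promoter shared by RpL32, a protein of the large ribosomal subunit, and CG7943 followed (3R, 30046055 to 30046470, signal 451). Among the other peaks of this group were CG1965 with CG1105 with 374, Gp150 with 354, Mic26-27, a part of the complex that shapes mitochondrial cristae, with CG5916 with 353, CG14441 with 352, and the Sry-alpha, Sry-beta and janA cluster with 340. In replicate 1 the peaks named here ranked between 1 and 16, and in replicate 2 between 1 and 25.

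Strong peaks away from any TSS were few. The strongest of them (X, 758828 to 759130, signal 282, rank 29) was intergenic, 607 bp from the TSS of CG5273. Another lay in a 3' UTR of CG16989 (X, 796348 to 796708, signal 248), and an intergenic peak lay 19565 bp from the nearest TSS, that of CG43402 (2L, 1462143 to 1462413, signal 225). The remaining 2 were in a 3' UTR where CG9166 and Ptp61F overlap (3L, 1351992 to 1352331, signal 209) and 2061 bp from Sfp79B (3L, 22078125 to 22078372, signal 194). None of these 5 had TATCGAT within 100 bp of the summit. That is not particular to them. Of the 10 strongest peaks, those at MESK2, CG1965 with CG1105, Mic26-27 with CG5916, and CG14441 also lacked it, and 54.6% of all summits had it.

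Which genes were bound was asked with gene lists. In all, 2418 of 13945 protein-coding genes (17.3%) were bound. Of the lists, 5 were bound more often than other genes. Of spliceosome and snRNP protein genes 19 of 33 (57.6%, 95% interval 39.2 to 74.5) were bound (odds ratio 6.51, adjusted exact p = 1.22e-06), the strongest being Sf3b1 with a signal of 201, LSm1 with 168, Sf3a1 with 151 and SmE with 144. All 4 of these peaks lie at promoters shared with another gene, which are Nle, Xpd, Irc and CG34132 in the same order, and the TSSs of Xpd and CG34132 were the nearer ones. This list was set by symbol pattern and not by function, so it takes in LSm1 and misses LSm-4. Cytoplasmic ribosomal protein genes were bound at 39 of 93 (41.9%, 31.8 to 52.6, odds ratio 3.48, adjusted exact p = 1.58e-07), led by RpL32 with 451, RpL26 with 273, RpS7 with 222 and RpS2 with 211. That list was set by symbol pattern too, and its bound members include RpL24-like and RpLP0-like. Proteasome subunit genes were bound at 20 of 48 (41.7%, 27.6 to 56.8; odds ratio 3.43, adjusted exact p = 0.000286), led by Rpn6 with 511, Prosalpha7 with 273, Rpn10 with 200.1 and Prosbeta2 with 198. Rpn6 shares its peak with ave, Prosalpha7 with CG1671 and Prosbeta2 with mRpL39, whose TSS was nearer. Cell cycle genes were bound at 15 of 39 (38.5%, 23.4 to 55.4; odds ratio 2.99, adjusted exact p = 0.00629), among them the mitotic kinase aurA with 239, the replicative helicase subunit Mcm5 with 216, geminin, an inhibitor of origin licensing, with 150.2, and the checkpoint kinase BubR1 with 130.03. The aurA peak is shared with CG3281 and the Mcm5 peak with Art1. Of 21 genes listed beforehand as zinc finger genes with a ZAD domain, 11 were bound (52.4%, 29.8 to 74.3, odds ratio 5.26, adjusted exact p = 0.000975). They were led by Sry-beta with 340, pad with 196, pita with 154 and dwg with 126. Whether each listed gene encodes that domain was not checked, and the list holds CG2129 itself, which was not bound. Sry-beta shares its peak with Sry-alpha and janA, pad with SF2 and pita with Dcp-1, and the TSSs of Sry-alpha, SF2 and Dcp-1 were nearer. The ribosomal and spliceosome calls held under every alternative tried. The proteasome call was lost with replicate 2's set alone (22.9% bound, adjusted exact p = 0.0851) and under a further alternative, as its range was 0.000277 to 0.206. The ZAD call was lost among peaks in both replicates' sets (adjusted exact p = 0.0581, range from 0.000308). The cell cycle call was lost with the background limited to genes with a ranked peak at a TSS (adjusted exact p = 0.0919, range from 0.00164). Over all lists, those more and less often bound, 4 calls were lost among peaks in both replicates' sets and 3 among peaks at or above the median signal.

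Segmentation, chemosensory, immune effector and histone genes were bound less often than other genes. None of 29 segmentation and gap genes was bound (upper bound of the 95% interval 11.9%; adjusted exact p = 0.0146), among them D, Kr, btd and cad, although 26 of the 29 had a peak in the ranked list. That call rested on few genes: the adjusted exact p was 0.0851 with replicate 2's set alone and 0.177 with replicate 1's set alone, where 3.45% were bound (range over alternatives 0.00149 to 0.185). Chemosensory receptor and odorant-binding protein genes were bound at 2 of 230 (0.87%, 0.105 to 3.11; odds ratio 0.041, adjusted exact p = 3.4e-15). Of these 2, Ir31a shares its promoter peak with LSm-4 and CG17768, and Ir76a shares one with CG14102, while Gr10a, Gr10b, Gr21a and Gr22a were unbound. Immune effector genes were bound at 1 of 45 (2.22%, 0.0562 to 11.8; adjusted exact p = 0.0125), PGRP-LE with a signal of 87.4, while AttA, AttB, AttC and AttD were unbound. With replicate 2's set alone the immune list had an adjusted exact p of 0.0851 (range over alternatives 0.00476 to 0.552). Replication-dependent histone genes had 0 of 111 bound (upper bound of the 95% interval 3.27%; adjusted exact p = 1.25e-08), including His1:CG31617, His1:CG33801, His1:CG33804 and His1:CG33807. Only 2 of those near-identical copies had a peak even in the ranked list, and how reads from such copies were placed is not given in the sources used here, so binding there is uncertain, and with 1 gene per peak and neighbouring copies counted once the call was lost (adjusted exact p = 1).

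The other 13 lists did not pass. Insulator and architectural protein genes were bound at 7 of 20 (35.0%, adjusted exact p = 0.123), and those 7, named after their values were seen, were BEAF-32, CTCF, Cp190, Dref, dwg, mod(mdg4) and pita. This list passed with the conservative set (45%, adjusted exact p = 0.00834) and with the set of replicate 2 or of replicate 1 alone (40% in both; adjusted exact p = 0.00573 and 0.0158), over a range of 0.00573 to 0.477. Oxidative phosphorylation genes were bound at 22 of 87 (25.3%, adjusted exact p = 0.123), the strongest being COX7A with 203, at a promoter shared with Arl2, and passed with replicate 2's set alone (21.8%, adjusted exact p = 0.0336). Heat shock protein genes were bound at 7 of 26 (26.9%, adjusted exact p = 0.288), led by the co-chaperone gene DnaJ-1 with 291. Dosage compensation genes were bound at 2 of 6, with msl-1 at 131, and piRNA and germline genes at 3 of 19, with tej at 140. Dorsoventral patterning genes stood at 4 of 29, with tin at 101.1, maternal determinants at 3 of 22, with exu at 102 (shared with galla-1, whose TSS was nearer), and pioneer factors and chromatin activators at 1 of 10, Iswi with 163. Cellularisation and sex determination genes were at 1 of 16, which was Sry-alpha with 340. Muscle structural genes had 1 of 21 bound (Tm1, at a promoter shared with MRG15, signal 44.3) and differentiated neuron genes 1 of 25 (eag, shared with CG9030, signal 84.2). Hox genes had 0 of 11 and chorion and yolk protein genes 0 of 19.

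**Figure D3:**
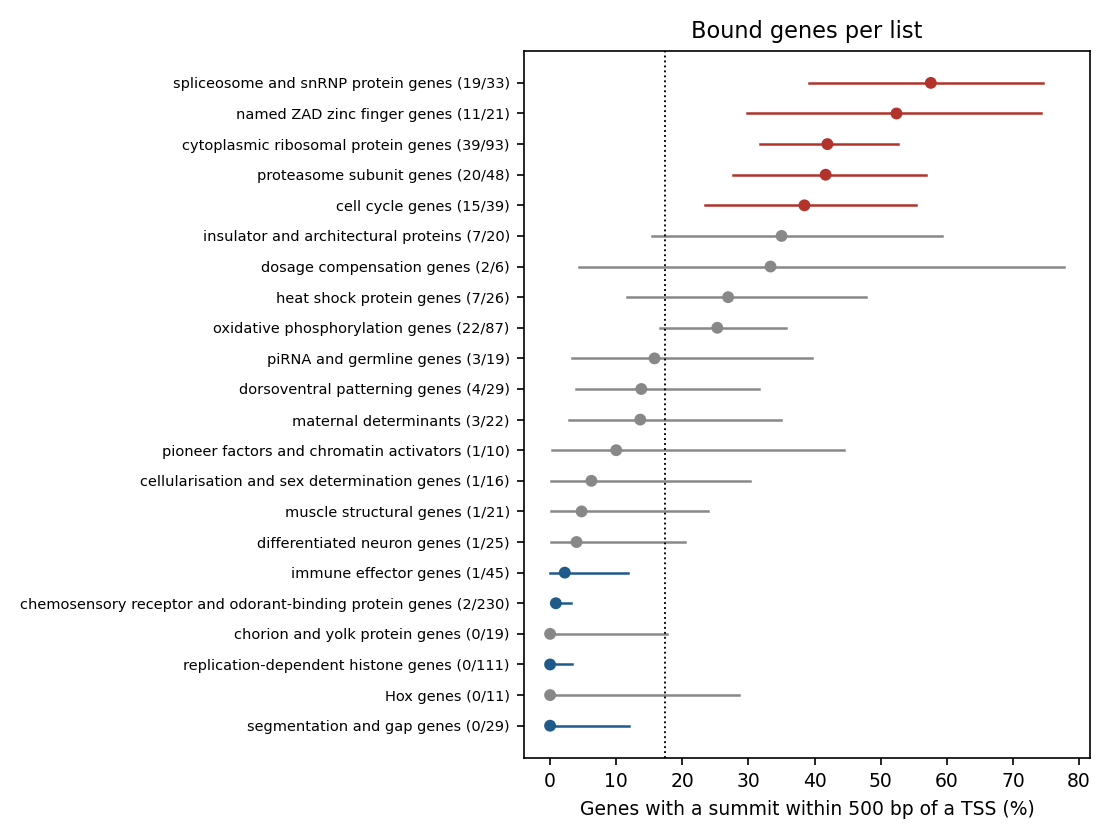
Percent of genes in each list with a summit within 500 bp of a TSS (x axis), with the exact 95% interval as a line and bound over measured genes beside each name. Red marks lists bound more often than other genes, blue less often and grey no call; the dotted line is the 17.3% of all protein-coding genes, and spliceosome genes lead with 57.6%.

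Head to head genes stood out. Of 3815 protein-coding genes with a divergent neighbour, 1417 (37.1%) were bound, against 9.88% of the 10130 others (odds ratio 5.39, p = 7.71e-284, Fisher's exact test). Genes of such a pair can share a peak, and 953 of the pooled peaks lay within 500 bp of TSSs of 2 or more genes, so the genes are not independent. Both distances are 500 bp, so a peak at 1 gene of a pair often marks its partner too. This raises the bound share of head to head genes by construction. How much of the odds ratio it makes was not tested, since no alternative gave each peak to 1 gene here. By class, 17.3% of protein-coding genes were bound against 3.72% of all other genes (odds ratio 5.43, adjusted exact p = 4.26e-136). Non-coding RNA genes (81 of 3261, 2.48%), snoRNA genes (8 of 269, 2.97%), pseudogenes (9 of 268, 3.36%) and rRNA genes (0 of 99) were bound less often, with adjusted exact p from 7.41e-133 to 8.42e-07. Only genes on arms X, 2L, 2R, 3L, 3R and 4 were counted, so any rRNA gene on an unplaced scaffold was left out. The strongest peak of the pooled ranked list lay on such a scaffold (signal 730). How reads from any near-identical rRNA copies were placed is not given either, so binding at rRNA genes is uncertain. For snRNA genes the count was 1 of 32 (adjusted exact p = 0.0769), and within 200 bp it was 0 and passed (adjusted exact p = 0.0321). Of tRNA genes 58 of 290 (20%) were bound, above the 14.1% of other genes (odds ratio 1.53, adjusted exact p = 0.00745). These 58 genes rest on only 32 peaks. With promoters taken as 200 bp the call was lost (14.1% of tRNA genes bound, adjusted exact p = 0.274), and with 1000 bp it was kept (24.8%). The direction turned among peaks at or above the median signal, where 2.76% of tRNA genes were bound, fewer than other genes (adjusted exact p = 0.000154), and among peaks in both replicates' sets (3.10%, adjusted exact p = 0.000454). With replicate 2's set alone 7.24% were bound, below other genes without passing (adjusted exact p = 0.19), and with replicate 1's set alone 16.2% (adjusted exact p = 0.0535).

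The summits carried a palindrome. TATCGATA, the DNA replication-related element (DRE) that the factor DREF binds, lay within 100 bp of 662 of 2066 summits (32.0%), against 12 windows (0.581%) 1000 bp away (adjusted exact p = 3.02e-178, exact McNemar test). The shorter TATCGAT, which holds the CGATA core known for the insulator protein BEAF-32, lay at 1128 summits (54.6%) against 62 windows. GC-matched promoter peaks below the threshold had TATCGATA in 87 of 2066 windows (4.21%; odds ratio 10.7, 95% interval 8.49 to 13.5, adjusted exact p = 1.24e-130, Fisher's exact test). TATCGATA was centred on the summit, at a median distance of 30.5 bp, with 43.8% of those peaks having it within 25 bp. The share with TATCGATA was 16.2% (95% interval 13.2 to 19.7) among the 517 weakest peaks, and 33.5%, 41.7% and 36.8% in the next 3 classes of about the same size by rising signal.

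Other promoter elements were commoner at summits than 1000 bp away. The sequence CARCCCTR was at 6.78% of summits against 0.678% (adjusted exact p = 5.63e-27) and was also above the weaker promoter peaks (2.32%, adjusted exact p = 2.82e-11). CAKCNCTR, the core of motif 7 of the fly core promoter set, was tested only after seeing the data. It was at 33.8% of summits against 6.53% (adjusted exact p = 6.27e-107) and 8.37% of weaker promoter peaks (odds ratio 5.58, exact p = 8.04e-94). The M1BP site YGGTCACACTR was at 3.78% against 0.387% (2.42% at weaker promoters, adjusted exact p = 0.0429). Motifs 5 and 6, at 3.34% and 1.36% of summits, were above the windows 1000 bp away but not distinguishable from weaker promoters (adjusted exact p = 0.337 and 0.713). Caudal's TTTATG was above the distant windows (16.6% against 13.3%, adjusted exact p = 0.00727) and below the weaker promoters (22.8%, adjusted exact p = 2.69e-06). Zelda, the activator of early zygotic genes, had its site at 5.61% of summits and 5.37% of distant windows (adjusted exact p = 0.78), and GAGA, TATA box, Initiator, Dorsal, Runt, AP-1, CTCF and Su(Hw) sites did not pass against distant windows. GAGA sites were below the weaker promoters (2.81% against 4.36%, adjusted exact p = 0.0308), and below distant windows with replicate 2's set alone (adjusted exact p = 0.00574), among peaks in both replicates' sets (0.0041) and among peaks at or above the median signal (0.00235). TATA box sites (3.92% against 3.10%) were above distant windows with replicate 2's set alone (adjusted exact p = 0.00378), among peaks in both replicates' sets (0.0126) and with overlapping peaks merged (0.00732). CTCF sites (0.823% against 0.29%, adjusted exact p = 0.0578) passed among peaks at or above the median signal (0.0127), with overlapping peaks merged (0.00515) and within 200 bp of the summit (0.0199), where Runt sites passed too (0.0135). Twist (5.71% against 10.6%), Bicoid (5.13% against 7.60%), Zeste (22.8% against 27.2%) and Stat92E sites (4.99% against 6.68%) were lower at summits than in distant windows. Against weaker promoters Twist sites passed (7.94% there, adjusted exact p = 0.0217) and Bicoid, Zeste and Stat92E sites did not (0.16 for each). The Stat92E difference was lost under every alternative tried (adjusted exact p from 0.0947 to 0.84). That of Caudal was kept only with replicate 2's set alone and within 200 bp of the summit, and lost otherwise (0.0611 to 0.574). The Zeste difference was lost with the conservative set (adjusted exact p = 0.0611), with replicate 1's set alone (0.116) and within 50 bp of the summit (0.213), and that of Bicoid within 50 bp (0.22). Among the 938 peaks without TATCGAT the differences of Twist, Bicoid, Zeste, Stat92E and Caudal missed the threshold (adjusted exact p from 0.0656 for Twist to 0.648 for Stat92E). With fewer peaks that does not show that they were absent, and Twist sites were at 6.29% against 9.17% there and Bicoid sites at 6.08% against 7.78%.

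**Figure D4:**
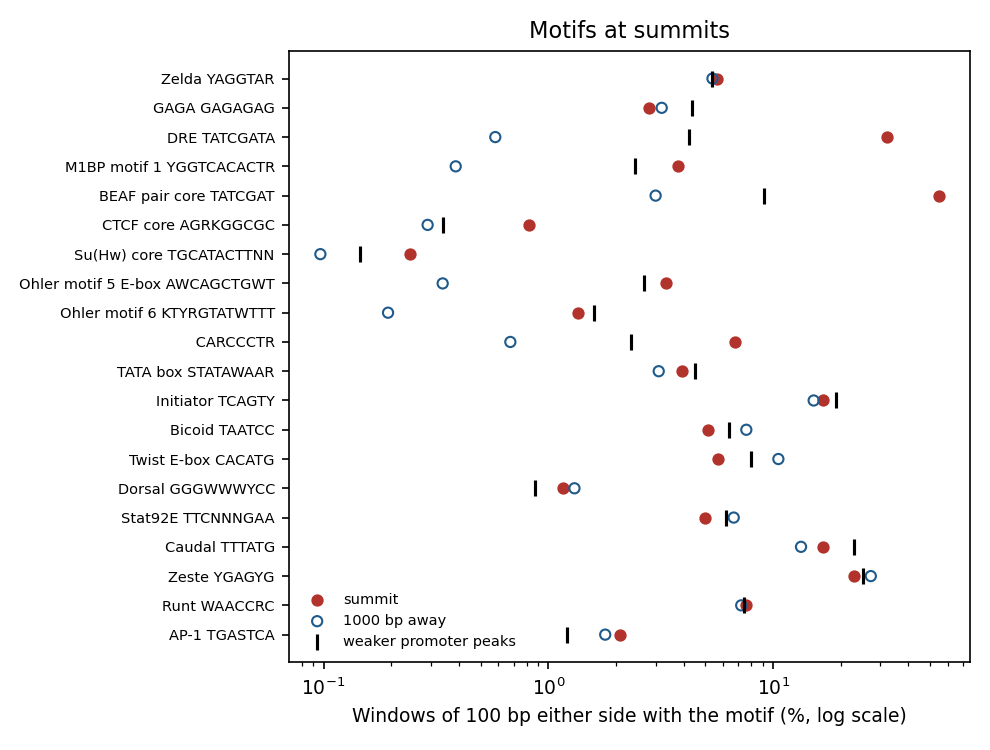
Percent of windows within 100 bp of a point that hold each motif (x axis, log scale), for pooled summits (red), points 1000 bp away (blue circles) and GC-matched weaker promoter peaks (black ticks). TATCGATA stands at 32.0% of summits, 0.581% of points 1000 bp away and 4.21% of weaker promoters.

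Without any preset motif, 1241 of 15334 8-mers were higher at summits and 1013 lower than in windows 1000 bp away. The 8-mers were not compared with weaker promoter peaks, so how many of them set promoters in general apart from nearby sequence was not tested. TATCGATA led, followed by ATCGATAG (31.1% against 0.678%), ATATCGAT (23.9% against 1.16%) and ACTATCGA (19.2% against 0.678%). Of the first 20, 19 held part of the palindrome. The exception was CATCTCTA (8.28% against 0.339%, adjusted exact p = 4.62e-39), which matches CAKCNCTR.

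**Figure D5:**
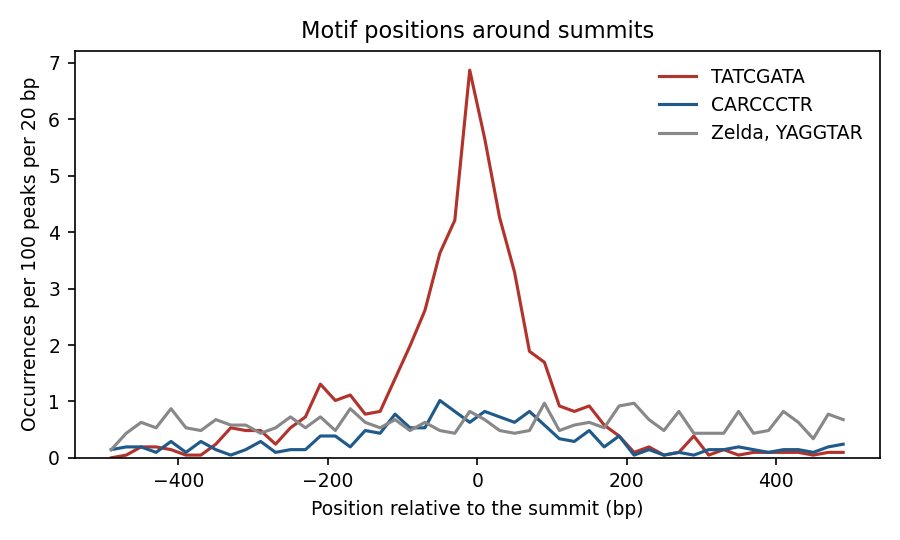
Occurrences of TATCGATA, CARCCCTR and the Zelda site per 100 peaks in bins of 20 bp (y axis) by position relative to the summit (x axis, bp). TATCGATA peaks at the summit, where its median distance is 30.5 bp, and the Zelda site stays far below it there.

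By chromosome arm, X held 425 peaks (20.6%, 95% interval 18.8 to 22.4), above its 17.1% of bases and 16.4% of TSSs (1.2 times by bases, adjusted exact p = 0.00017, exact binomial test). Arm 2R was at 1.13 times its share of bases (adjusted exact p = 0.0178) and 3L at 0.898 times (adjusted exact p = 0.0331), and neither differed from its share of TSSs (adjusted exact p = 0.876 and 0.519). The 3L call was lost under every alternative tried (adjusted exact p from 0.0592 to 0.352), and the 2R call was kept only with the conservative set and with peaks in both replicates' sets (lost otherwise, 0.05 to 0.501). Arm Y had 0 peaks (upper bound of the 95% interval 0.178%) against 2.49% of bases. Y also held 0.00837% of the ranked peaks, and against that share the call was lost (adjusted exact p = 1). Arms 2L, 3R and 4 did not pass against bases, and 2L lay below its share of TSSs (0.847 times, adjusted exact p = 0.00129). Arm 4 stood at 0.548 times its share of bases (adjusted exact p = 0.0593), and passed as lower with replicate 2's set alone (0.306 times, adjusted exact p = 0.0192) and among peaks in both replicates' sets (0.28 times, adjusted exact p = 0.0446). The excess on X was not past the threshold for peaks at or above the median signal (1.15 times, adjusted exact p = 0.0666) or for peaks in both replicates' sets (1.13 times, adjusted exact p = 0.0798).

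At its own gene, CG2129 had no peak in the pooled set or in either replicate's thresholded set. The conservative set had 2 within 5 kb, the stronger with a summit at X 8145626, 213 bp upstream of the TSS, and a signal of 41.4 (rank 1683 of 2017). The same summit was in the pooled ranked list without passing (−log10 IDR 1.53). None of the neighbours within 5 kb, which are CG10959, CG15336, CG17982, Gbeta5, Smox and alpha-PheRS, was bound in the pooled set.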

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

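The counts here were made after the lists had been seen, in entries that the comparisons do not use, and no test was run on them. Replicate 1's thresholded set held 6 peaks on the mitochondrial genome, with signals from 405 to 8640, above the 333 of its strongest peak on an arm. Of these entries, 3 share the interval 1309 to 3133 and differ in the summit, so they are not independent. Neither of replicate 2's lists nor the pooled ranked list held any mitochondrial peak. The pooled ranked list held 137 peaks on unplaced scaffolds, and its strongest peak of all (signal 730) was among them, as was the strongest of replicate 2's ranked list (signal 759). No peaks of this kind entered the comparisons.

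In the pooled ranked list 50 peaks passed the IDR of 0.01 and were missing from the thresholded set. Of these, 47 lay on the arms, 40 of them within 500 bp of a TSS, and 25 had TATCGAT within 100 bp of the summit. Their median signal was 91.6. The strongest on the arms lay at kibra (3R, 14724215 to 14724573, signal 379, which would have ranked 6th), osa (3R, 17718224 to 17718642, signal 298), nmo (3L, 7978568 to 7979097, signal 271), Bicra and Spec2. These names were chosen after their values were seen. Soft-masked sequence made up 15.5% of them on average and 17.6% of the main peaks. No explanation was tested.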

How the results depend on the processing

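Of the alternatives for the main values, 85 kept direction and call, or a count within 1.5 times, 27 moved and 3 lost the call; merging overlaps, leaving out TATCGAT peaks and CAKCNCTR as motif 7 were chosen after seeing the data. The promoter share, head to head odds ratio and replicate overlaps kept their call under every alternative tried. None of these gave each peak to 1 gene for the head to head genes, so partners that share a peak still count together there. Leaving out either replicate gave 1346 to 1675 peaks, 2 to 3 arms past the threshold (main 4), a log2 promoter difference of 0.20 to 0.32 (permutation p = 0.0879 without replicate 1), 2 to 3 lists bound less often (main 4), 2 to 4 motifs lower (main 4) and 324 to 670 8-mers lower (main 1013). Peaks at or above the median signal numbered 1033 and gave 1 arm, a promoter difference of 0.067 (permutation p = 0.64; narrowed by construction, as the cut is on signal), 2 lists bound less often and 181 8-mers lower. Peaks in both replicates' sets gave a promoter difference of 0.13 (permutation p = 0.389), 3 lists bound more and 2 less often, and 816 8-mers higher and 173 lower; these sets are smaller, which alone lowers counts. The conservative set gave 2 motifs lower, and a 50 bp window 1. Merged peaks gave 2 arms, and expected shares from ranked peaks 1. Lists bound less often numbered 2 with the ranked background, 2 with the nearest TSS only and 1 with 1 gene per peak and clusters counted once together. With 7-mers 1691 were lower. Peaks without TATCGAT gave 4 motifs higher and 1 lower, which is TATCGAT itself by construction, and 382 8-mers higher and 35 lower, where 8-mers with TATCGAT are at 0 by the same construction. Over the 11080 matched peaks of the 2 ranked lists the replicates' rho was 0.487. The excess at tRNA genes (20%) reversed among stronger peaks (2.76%), in peaks of both replicates (3.10%) and without replicate 1 (7.24%, exact adjusted p = 0.19; leaving out either replicate gave 7.24% to 16.2%); the cause was not tested for this or the other changes. Among named genes and single lists, motifs, arms and classes, 647 values kept their call, 59 lost it, 19 gained it, 3 reversed and 10 named peaks were lost; the genes whose peak was lost were Ir31a, Ir76a, Tm1 and eag. Read depth is unknown, so what it limits cannot be given. No paired analysis was possible because the series has 1 group.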

Other observations

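The peaks without TATCGAT, the sequence CAKCNCTR, the peaks at tRNA genes and the odds ratios of the pooled lists were examined only after the main results were seen, and the other tests of explanations were set before their results were seen. The 938 peaks without TATCGAT within 100 bp of the summit still carried related sequence. AACTATCG was in 12.5% of them against 0.853% of windows 1000 bp away (exact adjusted p = 4.87e-23, McNemar test) and ACTATCGC in 7.04% against 0.959%. Next to these stood CATCTCTA (10.7% against 0.959%, exact adjusted p = 7.49e-18), AGAGATGG (7.57% against 0.64%), GGTCACAC, which is part of the M1BP site (5.54% against 0.426%), and CAGCCCTG (3.62% against 0). CAKCNCTR, the core of motif 7 of the fly core promoter set, was in 30.3% of them against 7.36% (exact adjusted p = 6.35e-37), and the full M1BP site in 3.3%. CATCTCTA and CAGCCCTG match CAKCNCTR, and AGAGATGG overlaps its reverse complement. Zelda sites were in 5.76% against 5.44% (exact adjusted p = 0.883).

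Peaks within 500 bp of a tRNA gene's TSS numbered 32. They were weak, with a median signal of 52.8 against 78.1 for the other peaks. By rising signal, the 4 classes of about the same size held 14, 14, 3 and 1 of them. TATCGAT lay within 100 bp of the summit at 3 of the 32.

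TATCGATA at the summits was weighed first, and since the series has 1 group no biological explanation from the design was tested. GC content common to fly promoters is argued against as the whole account, since the odds ratio over GC-matched weaker promoter peaks was 10.7 (95% interval 8.49 to 13.5). Those weaker peaks lay within 500 bp of a TSS but were not matched on distance from it. Promoter sequence that varies with that distance therefore stays open. A summit position set by the gene start alone is argued against too. Among 860 promoter peaks with TATCGATA within 500 bp of the TSS, the median distance from motif to summit was 45.5 bp, against 65.8 on average (95% of exchanges from 61.5 to 70) after exchanging the offsets between peaks (p = 0.001, one-sided permutation test, the smallest it can give). Promoter peaks with TATCGATA were stronger by 0.36 on the log2 scale (p = 1e-05, permutation test, the smallest it can give). Their median was 92.6 (n = 639), against 72.0 without it (n = 1315). Binding that follows the motif could give this difference, but the share with TATCGATA did not rise throughout. By rising signal it was 16.2%, 33.5%, 41.7% and 36.8% of all peaks in the classes given above. Weaker peaks that overlap a stronger one, which are weighed next, were kept in this comparison. How much they add to the difference was not tested, so binding that follows the motif stays open. Whether CG2129 contacts TATCGATA or comes down with another protein was not tested.

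Weaker peaks that overlap a stronger one were weighed next, as 1 site written as 2 peaks. Over 252 such pairs the summits lay a median of 202 bp apart and the stronger signal was 5.64 times the weaker. TATCGAT lay within 50 bp of 8.73% of weaker summits, 3.57% of points mirrored across the stronger summit and 41.3% of stronger summits (p = 0.0192, exact McNemar test of weaker against mirrored). This argues against a double entry as the account of every pair, and most pairs stay open. No biological explanation was tested.

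The split between gene lists was weighed last, and no biological explanation was tested. If only promoters with some enrichment could be called, the lists would lose their calls against genes with a ranked peak, and 6 of the 9 that passed kept theirs, between the bounds set beforehand. The 6 were the segmentation, ZAD, ribosomal, proteasome, spliceosome and chemosensory lists. By the rule set beforehand, 6 of 9 decides nothing for the lists together. Read list by list, which was not set beforehand, the calls of these 6 held among genes with a ranked peak. That argues against this explanation as their whole account, and for the other lists it stays open. Having a ranked peak does not make enrichment equal between genes. Against that background the 5 lists bound more often had, pooled, an odds ratio of 2.83 (95% interval 2.13 to 3.75) and the 4 bound less often 0.0713 (0.0226 to 0.225). Those lists were pooled because they had passed with the same bound genes, so the pooled values add no separate evidence. How much of each difference this explanation makes stays open. The odds ratio of spliceosome genes fell from 6.51 to 3.69 and that of cell cycle genes from 2.99 to 2.22, and only 2 histone genes were left. Promoter content of TATCGAT was tested for the 5 lists bound more often. Log odds ratios stratified by it were a median of 0.978 of the unstratified ones, from 0.665 for the proteasome list to 1.06 for the ZAD list. Every stratified odds ratio stayed above 1, with cell cycle genes lowest in its interval (2.47, 95% interval 1.18 to 5.18). This argues against the exact sequence as the whole account. How much it makes up cannot be read from 0.978, since odds ratios can rise within strata of a strong predictor. TATCGAT was at 75.1% of bound and 29.2% of all protein-coding genes. Related sequences such as AACTATCG were not counted, so wider motif content stays open.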
